A study of Mus musculus with 16 samples.

How the data were processed

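RNA-seq was carried out on whole uteri of ovariectomized mice of 2 strains that carry a Pgr-Cre driver and a Cre-activated transgene, either for progesterone receptor isoform A (called PRA here) or for isoform B (PRB), per the labels. Uteri were collected 6 h after oil or progesterone (P4), 2 weeks after ovariectomy, and the labels name 4 biological replicates in each of the 4 groups, 16 libraries in all. In the labels all PRA libraries carry positions of row A and all PRB libraries of row B, and within each row the oil libraries come before the P4 libraries, so that position is confounded with strain and with treatment. No strain without a transgene was used here, so each strain is compared with the other and with its own oil group. The treatment protocol field of the labels speaks of mated females dissected on day 4 of pregnancy, whereas the titles, the sample characteristics and the series design give ovariectomy and 6 h treatment; the groups follow the latter, and the conflict could not be settled from the data.

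The deposited table gives FPKM (fragments normalized to transcript length and to sequencing depth) per feature and library. TopHat2 2.0.4, Cufflinks 2.0.2, Cuffdiff and the mm10 build are named in the submitters' processing notes, which give neither the role of each tool nor the order. The annotation behind the features, the strandedness of the counting and any scaling between libraries are not given in the sources used here. The table held 31274 features, of which 7717 were 0 in every library. Total FPKM lay between 499748 and 595748 per library, and the upper quartile between 14.5 and 15.1. No fragment counts were used here. The spacing of the lowest values of features longer than 800 bp with a single transcript implied 54.7 M to 66.6 M fragments per library after whatever scaling the authors applied, so that 1 FPKM of a 2 kb transcript rested on about 109 fragments in the library of lowest depth. A change of scale common to a whole library cannot be told from a change in depth by this means. In 291 features a value of 0 in one library stood beside a value over 5 in another, so a listed 0 need not mean that the RNA was absent. Features listed at 0 in all 4 libraries of a group are given without a fold change.

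Values were compared on the log2(FPKM + 1) scale with limma 3.58.1 in R 4.3.3, which understates the change of weakly expressed genes. Features with a mean of at least 1 FPKM over the 16 libraries were tested, 15408 in number. All 16 libraries entered 1 model with a mean for each group, and moderated two-sided tests with an intensity trend gave p-values, adjusted by Benjamini-Hochberg over all features tested. A feature is said to be called, and to have risen or fallen, where the adjusted p was under 0.05. The 5 contrasts were P4 against oil in each strain, PRB against PRA with oil, PRB against PRA with P4, and the difference of the P4 responses (PRB minus PRA). Log2 differences are given with their standard error from the fit (SE), and FPKM levels as mean ± SD of 4 libraries. With 4 libraries against 4, complete separation of 2 groups arises by chance in 2.86% of features.

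The contrasts, the rule for named genes and 28 gene lists were fixed before the data were examined. So were the alternatives, except the one without unmatched, microRNA and small nucleolar features. The rule named Pgr and, for each contrast, the 10 largest increases and decreases among called features with complete separation (for the difference of responses, among called features), and up to 4 called members of each list, or its 2 most expressed members where none was called; unnamed transcripts, Riken clones and predicted genes may be counted without a name. The rule sets which genes may be named, and the text names a part of them; 2 were also left out of the counts of results for such genes and are not reported here. Lists were tested against the remaining features with camera of limma at a preset correlation of 0.01, adjusted over 140 tests, and again with an estimated correlation. Fry tested each list by itself, without the remaining features. A list that did not pass camera may therefore still hold members that changed. Beside counts of called members, counts adjusted over the list alone are given. A further 6 lists were written after the data had been seen and are reported apart.

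In simulated data of 15408 features, changes of 0.5, 1 and 2 on the log2 scale were given to 67, 67 and 66 features. The procedure recovered 73.1%, 98.5% and 97.0% of them for the P4 response in PRA, and 3.76% of its calls were false. For the difference of responses the shares recovered were 46.3%, 73.1% and 95.5%, and 7.14% of calls were false. False calls made up 6.21% for the P4 response in PRB, 4.12% for the strains with oil and 2.41% for the strains with P4. The simulated features varied independently of each other, with normal noise and few changed features, so these shares need not hold in the data. Feature names were matched to GENCODE release M21 (GRCm38, the assembly also called mm10) for coordinates: 13738 tested features matched a symbol, 612 an older synonym, and 1058 neither. Features are named as in the deposited table. Alternatives covered the pseudocount, the filter on low values, 2 further scalings, a replicate block, the samples in the fit, robust variance estimation, a minimum fold change and leaving out each library in turn.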

Results

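The data were FPKM values of 31274 features in 16 whole-uterus libraries, 4 each from oil-treated and P4-treated mice of the PRA strain and of the PRB strain. Between 14807 and 15336 features reached 1 FPKM in a library. Total FPKM was 516178 ± 14041 in PRA oil and 515035 ± 5413 in PRB oil, against 583022 ± 10099 in PRA P4 and 588254 ± 7368 in PRB P4 (SD, n = 4). The first principal component held 57.3% of the variance and the second 8.31%. PRB P4 replicate 3 lay farthest from its group, at 42.6 on the second component.

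Pgr, the progesterone receptor gene (chromosome 9, 8899833 to 8968611, plus strand, mm10), was measured at 64.9 ± 5.52 FPKM in PRA oil, 73.9 ± 1.80 in PRA P4, 83.5 ± 4.49 in PRB oil and 112 ± 22.3 in PRB P4 (SD, n = 4). With P4, Pgr was higher in PRB than in PRA by 0.57 on the log2 scale (SE 0.12, limma, adjusted p = 0.00575). With oil the difference was 0.36 (SE 0.12, adjusted p = 0.588) and was not called over all features. The PRB oil values (79.5 to 87.6 FPKM) nevertheless all lay above the PRA oil values (56.8 to 68.9), so equal levels without hormone cannot be assumed. Pgr rose with P4 in PRB by 0.39 (adjusted p = 0.00807), whereas the change in PRA was 0.19 (adjusted p = 0.171) and the 2 responses did not differ past the threshold (0.21, adjusted p = 0.583). After quantile normalization the changes in PRA and PRB were -0.05 and 0.11, neither of them called, and with the libraries of the contrast alone the change in PRA was called. In PRB P4 replicate 3 Pgr stood at 78.5 FPKM, while the other 3 libraries of that group lay between 121 and 126, and without that library the difference of the 2 responses was 0.37 and was called. The values sum over the isoforms, so they do not separate receptor A from receptor B or the transgene from the endogenous gene.

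**Figure D1:**
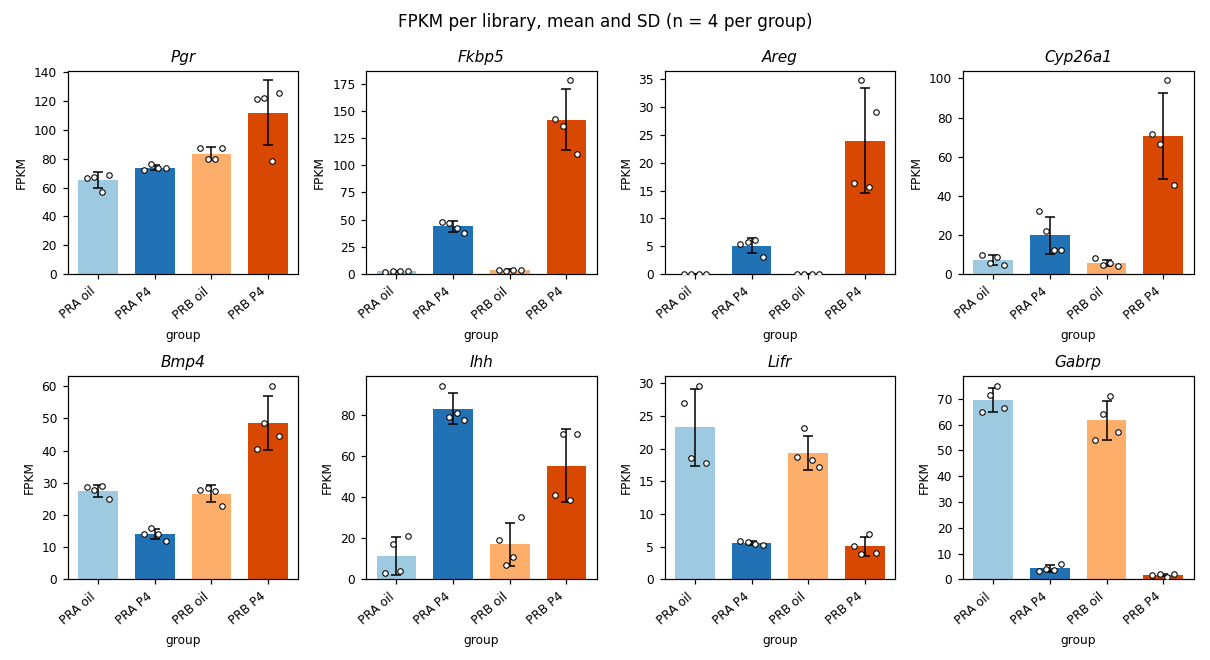
FPKM (y axis) of 8 genes in each library (points) of the 4 groups (x axis), with bars for the mean and error bars for the SD, n = 4. Fkbp5, Areg and Cyp26a1 were highest in PRB P4, Bmp4 was lower with P4 in PRA and higher in PRB, and Lifr and Gabrp were lower with P4 in both strains.

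The first comparison asked how the uterus of the PRA strain had responded to P4 after 6 h. Hsd11b2, the enzyme that inactivates glucocorticoids, rose from 12.5 ± 2.51 to 673 ± 50.0 FPKM (SD, n = 4; log2 change 5.65, SE 0.15, adjusted p = 4.91e-12). Fst, the activin-binding protein follistatin, rose by 4.86, the endocytic receptor gene Lrp2 by 4.28, the decoy receptor gene Il13ra2 by 4.04 and Irg1, the itaconate-producing enzyme, by 3.92. Gabrp, a GABA-A receptor subunit, fell by 3.78, from 69.4 ± 4.70 to 4.21 ± 1.25 FPKM (SD, n = 4; SE 0.17, adjusted p = 2.62e-10). In all, 10760 of 15408 features were called, 5646 higher and 5114 lower with P4, of which 1069 and 1121 changed by at least 1 on the log2 scale. After median-ratio scaling 5238 were called higher and 5553 lower, so the balance of directions depends on the scaling.

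Among the other largest increases in PRA were Adamtsl2 (4.55), the mitochondrial folate enzyme gene Mthfd2 (4.51), the sialic acid lyase gene Npl (4.19), the endoplasmic reticulum gene Sdf2l1 (4.02) and the amino acid transporter gene Slc6a14 (3.72). The largest decreases included Hpgds (-3.37), which makes prostaglandin D2, C1ql2 (-3.29), Nsg2 (-3.26), Gucy2g (-3.21) and the stromelysin gene Mmp10 (-3.14). Hpgds varied in oil, at 29.2 ± 21.3 FPKM (SD, n = 4). The rule also took the microRNA features Mir1247, listed at 0 in all P4 libraries and at 95.2 ± 93.0 FPKM in PRA oil (SD, n = 4), and Mir670, which was called lower with P4 but listed at 0 in 2 of 4 PRA P4 libraries, so its fold change depends on the pseudocount.

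Of the 18 progesterone-responsive genes in the list fixed for the uterus, 15 rose in PRA and none fell (also 15 adjusted over the list alone), with a median of 2.49 (camera, adjusted p = 0.000259; adjusted p = 0.154 with an estimated correlation). Of 15 targets that several steroid receptors share, 10 rose and 1 fell (10 and 1 adjusted over the list alone), among them Fkbp5, a receptor co-chaperone (3.68), the kinase Sgk1 (2.49), Errfi1 (2.33) and Zbtb16 (1.94). In the hedgehog list Ihh rose by 3.12 (SE 0.51, adjusted p = 6.71e-05), as part of 5 higher and 1 lower of 12. Among 10 EGF-family genes 4 rose and 4 fell, with Areg, an epidermal growth factor receptor ligand, at 2.50 and Erbb2 at -0.90. Retinoid genes went both ways, 3 higher and 7 lower of 14 (3 and 8 adjusted over the list alone), with the retinoic acid-producing Aldh1a2 at 3.02 and the retinoic acid-degrading Cyp26b1 at -1.40. In the WNT and BMP list 9 of 22 fell and 4 rose, with Wnt7a at -1.74 and Rspo3 at -1.68. Apart from the progesterone-responsive list, none of these lists passed camera in PRA. The camera adjusted p was 0.0807 for steroid receptor targets, 0.605 for hedgehog, 0.852 for EGF-family, 0.644 for retinoid and 0.213 for WNT and BMP genes. Fry called steroid receptor targets (adjusted p = 1.88e-05) and hedgehog genes (0.00167) higher, and WNT and BMP genes (0.000187) lower. It did not call EGF-family (0.697) or retinoid genes (0.108). Fkbp5, Sgk1 and Zbtb16 belong to the progesterone-responsive list as well.

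LIF signalling genes, which carry the leukemia inhibitory factor signal, held 6 lower and 2 higher members of 12 in PRA (the same counts adjusted over the list alone). Pim1 fell by 1.89 (SE 0.14, adjusted p = 1.93e-08) and the receptor gene Lifr by 1.86 (SE 0.17, adjusted p = 2e-07). Among 19 cell cycle genes 12 rose and none fell (10 adjusted over the list alone), with Top2a at 1.81, Rrm2 at 1.78, Tyms at 1.54 and Mcm5 at 1.33; the PRA oil libraries spread widely, Mki67 reaching 1.52, 7.52, 1.44 and 11.2 FPKM in replicates 1 to 4. Estrogen-responsive genes held 6 higher and 3 lower of 14, with Sprr2f at 3.48, Igf1 at 2.14 and Odc1 at 1.58. Matrix remodelling genes held 2 higher and 4 lower of 13, with Mmp9 at -2.16, Mmp11 at -1.86 and the protease gene Adamts1 at 1.81. Of 15 clock genes 4 rose and 7 fell, with Npas2 at 1.91, Dbp at -2.05, Nr1d1 at -2.0 and Per3 at -1.67. Interferon-stimulated genes held 5 lower of 14, with Ifit3 at -1.53. None of these 6 lists passed camera in PRA. Fry, which sets no list against other features, called cell cycle (adjusted p = 0.0174) and estrogen-responsive genes (0.0025) higher. It called LIF signalling (0.00113) and matrix remodelling genes (1.7e-07) lower, but not clock (0.57) or interferon-stimulated genes (0.163).

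The remaining lists in PRA were as follows, and none of them passed camera. Of all tested features 69.8% were called in PRA, so list counts near that share, here and above, are not particular to a list. Steroid receptors and coregulators held 4 higher and 7 lower of 15, with Hsp90aa1 at 1.77 and Nr3c1 at -0.60. Regulators of contraction held 7 higher and 7 lower of 17, with Ptgs2 at 1.26 and Pln at -1.09, and contractile genes of smooth muscle 4 higher and 2 lower of 15. Hypoxia and angiogenic factors held 5 higher and 3 lower of 11, with Pgf at 1.65, ion and water transport genes 2 higher and 1 lower of 10, with Atp1b1 at 1.99, and immediate early and stress genes 5 higher of 12, with Hspa1b at 1.05. Among cell type markers, 5 of 15 epithelial genes rose and 5 fell, 5 of 13 stromal genes rose and 5 fell, 5 of 10 endothelial genes fell (Cldn5, -1.37), 4 of 6 mesothelial genes fell (Upk3b, -0.99), and 1 of 4 glandular genes rose (Sox17, 0.49; 2 genes without PRB P4 replicate 3). Leukocyte markers held 1 higher (S100a8, 1.40) and 1 lower (Csf1r, -0.61, lost under 6 of 17 alternatives) of 13 (1 and 3 without PRB P4 replicate 3). Of the ovary and oviduct markers 1 of 4 fell (Inha, -1.61), 2 of 3 skeletal muscle markers rose (Acta1, 2.27) and 1 fell, and none of 7 adipose or 4 red blood cell markers was called. For the lists in PRA given without such a value, the counts adjusted over the list alone were the same, except for hypoxia and angiogenic factors (5 higher and 5 lower), mesothelial markers (5 lower) and leukocyte markers (1 higher and 0 lower).

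**Figure D2:**
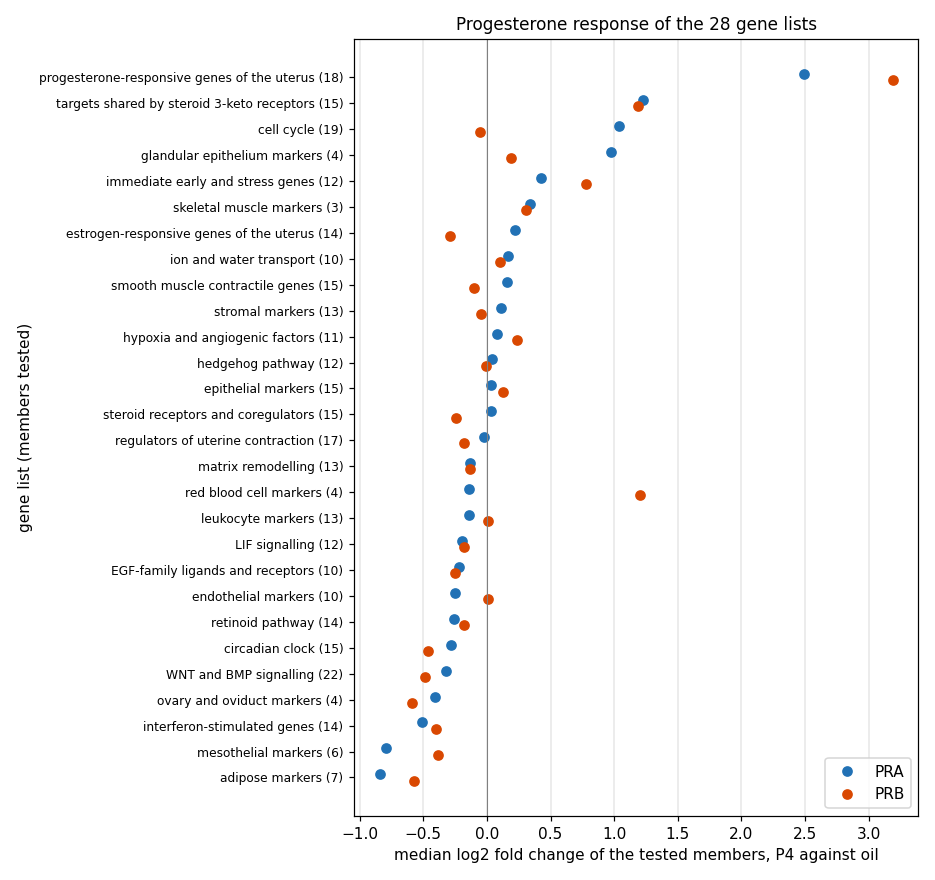
Median log2 fold change with P4 (x axis) of the tested members of each of the 28 gene lists (y axis, members tested in brackets) in PRA (blue) and PRB (orange). The progesterone-responsive list stood highest in both strains, at 2.49 and 3.19, and the cell cycle list at 1.04 in PRA and -0.06 in PRB.

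The second comparison asked the same of the PRB strain. Hsd11b2 rose from 16 ± 3.67 to 977 ± 122 FPKM (SD, n = 4; log2 change 5.86, SE 0.15, adjusted p = 2.21e-12). Fst rose by 5.55, Pate4 by 5.26, Il13ra2 by 5.24, Calca, which encodes calcitonin and its related peptide, by 5.11, Slc6a14 by 5.05 and Ms4a8a by 5.05. Gabrp fell by 4.56, the kinase gene Cdkl1 by 3.61, Nsg2 by 3.50, C1ql2 by 3.33, the hyaluronan-degrading Cemip by 3.22 and Stc1, a secreted glycoprotein, by 2.82. A total of 10647 features were called, 5577 higher and 5070 lower, with 1104 and 1005 changed by at least 1. After median-ratio scaling 5163 were called higher and 5562 lower.

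Calca in PRB P4 averaged 67.8 ± 76.4 FPKM (SD, n = 4), with 182 FPKM in replicate 3 and 18.2 to 36.6 in the others. The small RNA features taken by the rule were Snord83b and Mir429, called higher but each listed at 0 in 3 of 4 PRB oil libraries, and Mir681, called lower but listed at 0 in 2 of 4 PRB P4 libraries, so that their fold changes depend on the pseudocount, with Mir704 listed at 0 in every oil library and at 172 ± 103 FPKM in PRB P4 (SD, n = 4), and Mir7035 and Snord53 listed at 0 in PRB P4. The call of Mir429 was lost under 6 of 16 alternatives, with adjusted p up to 0.0704.

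The progesterone-responsive list held 15 higher and 1 lower of 18 in PRB (the same adjusted over the list alone), median 3.19 (camera, adjusted p = 7.35e-05; adjusted p = 0.154 with an estimated correlation); without PRB P4 replicate 3 the counts were 15 and 0. Steroid receptor targets held 10 higher of 15, with Fkbp5 at 4.96 and Sgk1 at 3.40 (camera, adjusted p = 0.0124; adjusted p = 0.842 with an estimated correlation). Areg rose by 4.50 in an EGF-family list of 4 higher and 5 lower of 10, and Ihh by 1.78 in a hedgehog list of 4 higher and 4 lower of 12 (4 and 3 adjusted over the list alone), with the receptor gene Ptch1 at -0.92. In the retinoid list, 4 rose and 4 fell of 14, with Aldh1a2 at 3.56, the retinoic acid-degrading Cyp26a1 at 3.41 and Aldh1a3 at -2.26. LIF signalling genes held 5 lower and 1 higher of 12, with Lifr at -1.77, Pim1 at -1.59 and the co-receptor gene Il6st at -0.62. The WNT and BMP list held 11 lower and 4 higher of 22, with Wnt7a at -2.64, Wnt16 at -1.84 and Lgr5 at -1.76. Of the cell cycle genes 2 rose (Tyms, 0.93; Pcna, 0.65) and 2 fell (Mcm6, -0.65, lost under 5 of 17 alternatives; Mcm7, -0.56), and 3 rose and 1 fell without PRB P4 replicate 3.

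Among the other lists in PRB, estrogen-responsive genes held 5 higher and 4 lower of 14, with Lcn2 at 2.43 and Greb1 at 2.29. Clock genes held 4 higher and 8 lower of 15, with Npas2 at 3.00, Per3 at -2.19 and Dbp at -2.03. Immediate early and stress genes held 8 higher of 12, with Zfp36 at 1.52, and interferon-stimulated genes 6 lower of 14 (5 adjusted over the list alone), with Ifit2 at -1.47. Steroid receptors and coregulators held 4 higher and 7 lower of 15, with the mineralocorticoid receptor gene Nr3c2 at -1.22 and Esr1, the estrogen receptor gene, at -0.80. Matrix remodelling genes held 1 higher and 5 lower of 13, with Mmp10 at -2.64, regulators of contraction 4 higher and 7 lower of 17, with Ptgs1 at 1.82 and Cacna1c at -1.14, ion and water transport genes 4 higher and 4 lower of 10, with Cftr at -1.01, and hypoxia and angiogenic factors 5 higher and 3 lower of 11, with Hif1a at 1.58. Smooth muscle genes held 2 higher and 3 lower of 15, epithelial markers 5 higher and 2 lower of 15 (Cldn3, 1.72), stromal markers 4 higher and 6 lower of 13 (Lum, -2.09), endothelial markers 2 lower of 10, mesothelial markers 2 lower of 6 and leukocyte markers 1 higher and 1 lower of 13. Without PRB P4 replicate 3 the smooth muscle list held 3 higher and 1 lower, the leukocyte list 1 and 3, and the LIF list 2 and 6. Glandular markers held 2 higher of 4, with Spink3 at 3.12 (SE 0.71). Spink3 averaged 20.1 ± 30.7 FPKM in PRB P4 (SD, n = 4). It was listed at 0 in 2 of 4 PRB oil libraries, so its fold change depends on the pseudocount. The ovary and oviduct list held 2 lower of 4, skeletal muscle 1 higher and 1 lower of 3, and adipose and red blood cell markers no called member. For the lists in PRB given without such a value, the counts adjusted over the list alone were the same, except for the cell cycle list (2 higher and 1 lower) and leukocyte markers (1 higher and 0 lower). Of all tested features 69.1% were called in PRB. Only the progesterone-responsive and steroid receptor target lists passed camera there.

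The 2 responses largely involved the same features: 9236 were called in the same direction in both strains, 4926 higher and 4310 lower, where independent lists would share 2044 and 1683, and 42 were called in opposite directions. After median-ratio scaling the shared features were 4524 higher and 4728 lower. Across all tested features the 2 log2 changes had a Pearson r of 0.863 and a Spearman rho of 0.882; features are not independent replicates. The responses share no library, but both use the same estimate of the spread for each feature.

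**Figure D3:**
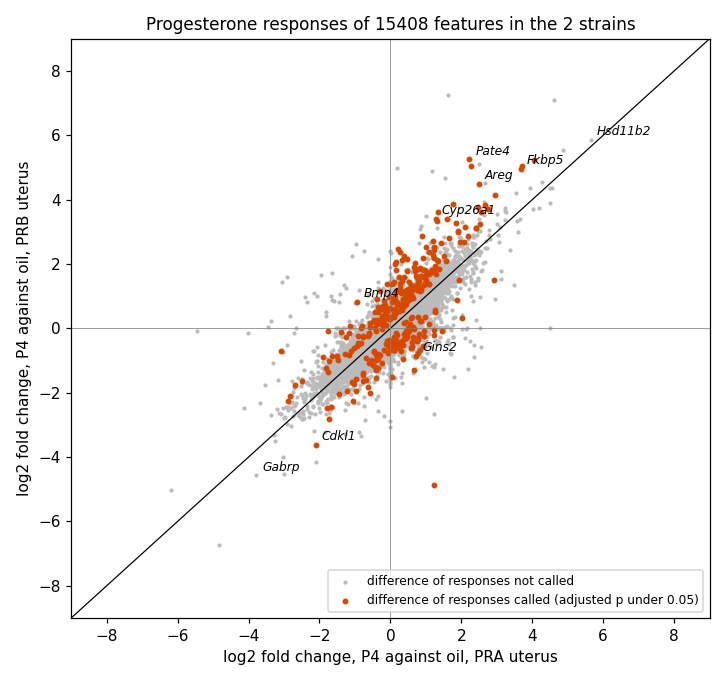
Log2 fold change with P4 in PRA (x axis) and in PRB (y axis) of each tested feature, with the line of equal response. Orange points are the 352 features whose responses differed (limma, adjusted p under 0.05), among them Pate4, Areg, Fkbp5, Cyp26a1 and Bmp4 above the line and Gins2 and Cdkl1 below it.

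Without P4 the 2 strains differed in few genes. Gbp2b, an interferon-inducible GTPase (chromosome 3, 142594847 to 142619179, plus strand), was at 8.06 ± 0.554 FPKM in PRA and 0.221 ± 0.0355 in PRB (SD, n = 4; log2 difference -2.89, SE 0.07, adjusted p = 5.61e-12). Gdpd3, which encodes a phospholipase (chromosome 7, 126766334 to 126775649, plus strand), was at 55.8 ± 10.5 and 3.84 ± 0.50 FPKM (SD, n = 4; -3.54, SE 0.55, adjusted p = 0.0183). The zinc finger gene Zfp868 on chromosome 8 was lower in PRB (-1.12), as were Armc6 (-0.53), Rdh13 (-0.38) and Ints10 (-0.33), while Tmem181b-ps (0.83), Zfp14 (0.56), Cacng7 (0.47), the ribosomal protein gene Rpl34 (0.42) and Tmem181a (0.36) were higher. Tmem181a and the pseudogene Tmem181b-ps are near copies whose reads may be shared, so their separate values are uncertain. Snord53 was listed at 0 in PRA oil and at 28 ± 0.428 FPKM in PRB oil (SD, n = 4).

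In total 18 features were called with oil, 6 higher and 12 lower in PRB (10 and 13 after quantile normalization). Of the 15408 tested, 802 had an unadjusted p under 0.05, a share close to the 0.05 that chance alone would give. The count was 8 without PRA oil replicate 2, 10 without PRA oil replicate 3, 9 without PRB oil replicate 2, 10 without PRB oil replicate 4, 29 without PRB P4 replicate 3, which shares the fit, 33 without a filter and 6 with the 8 oil libraries alone, and another split of the same 8 libraries called 880. Gdpd3 and Ints10 each lost the call under 6 of 17 alternatives, Zfp14 and Cacng7 under 4, Tmem181a under 3, Armc6 under 2, and Rdh13, Rpl34 and Tmem181b-ps under 1. No member of any of the 28 lists was called over all features, and 1 of the steroid receptors and coregulators was without PRB P4 replicate 3. By camera the list values stood higher in PRB for progesterone-responsive genes (median 0.23, adjusted p = 0.000199; adjusted p = 0.154 with an estimated correlation), steroid receptor targets (0.18, adjusted p = 0.000273; adjusted p = 0.542 with an estimated correlation) and interferon-stimulated genes (0.47, adjusted p = 8.39e-08; adjusted p = 0.757 with an estimated correlation). The same held for stromal (adjusted p = 2.2e-05; adjusted p = 0.301 with an estimated correlation), leukocyte (adjusted p = 0.00858; adjusted p = 0.842 with an estimated correlation), hedgehog (adjusted p = 0.00858; adjusted p = 0.542 with an estimated correlation) and cell cycle genes (adjusted p = 0.0403; adjusted p = 0.938 with an estimated correlation). Adjusted over the list alone, 1 leukocyte gene was higher and 1 retinoid gene lower.

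**Figure D4:**
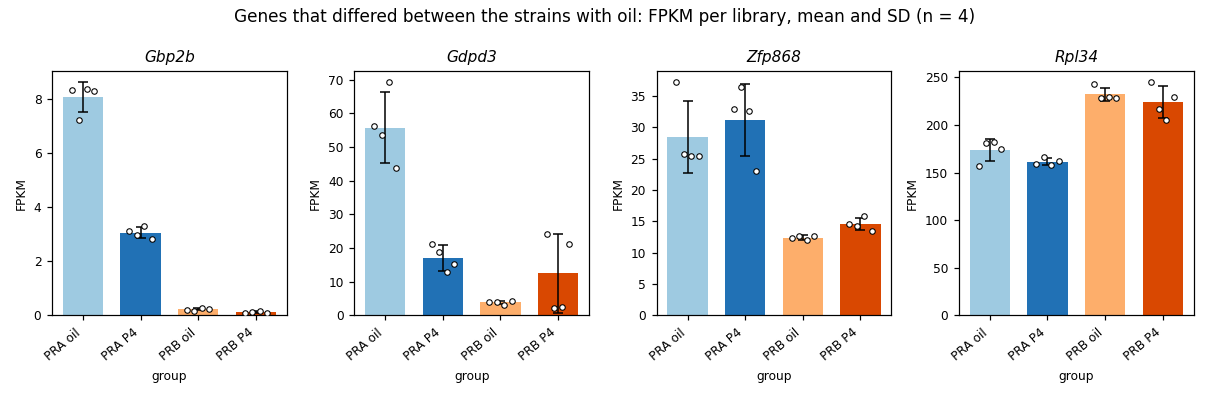
FPKM (y axis) of 4 genes in each library (points) of the 4 groups (x axis), with bars for the mean and error bars for the SD, n = 4. Gbp2b and Zfp868 were lower and Rpl34 was higher in PRB with oil and with P4, and Gdpd3 in PRB P4 took values of 24.1, 2.18, 2.44 and 21.3 FPKM.

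With P4 the strains differed more widely. Fkbp5 reached 43.7 ± 4.79 FPKM in PRA and 142 ± 28 in PRB (SD, n = 4; log2 difference 1.66, SE 0.15, adjusted p = 1.44e-05), and Areg 5.10 ± 1.40 and 24.0 ± 9.45 (1.99, SE 0.22, adjusted p = 9.44e-05). Bmp4, a bone morphogenetic protein, was higher in PRB by 1.71 (SE 0.11, adjusted p = 1.26e-06). Lower in PRB were Sprr2f, an epithelial cornified envelope gene (-2.27), Igj, the immunoglobulin joining chain (-2.17), and the DNA replication genes Dtl (-2.06) and Uhrf1 (-2.05). A total of 2471 features were called, 1194 higher and 1277 lower in PRB, of which 105 and 99 differed by at least 1. After median-ratio scaling 1328 were called higher and 1155 lower in PRB. Library positions followed the strains, row A for PRA and row B for PRB per the labels, with oil and with P4, so a difference between the strains and one between the rows cannot be told apart by these counts.

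Further genes higher in PRB with P4 were Pate4 (3.02), Ms4a8a (2.66), Calca (2.54), the protease gene Ctse (2.41), Cyp2j11 (2.28) and Acsbg1 (2.12). Ctse in PRB P4 averaged 137 ± 210 FPKM (SD, n = 4), and its call was lost under 3 of 17 alternatives. Further genes lower in PRB were Slfn9 (-2.11), the matrix gene Tnc (-2.01), Sprr2e (-1.88) and Gbp2b (-1.86). The microRNA features Mir709 and Mir704 were listed at 0 in all libraries of at least 1 group, and Mir135a-2, called higher in PRB, was listed at 0 in 3 of 4 PRA P4 libraries, so its fold change depends on the pseudocount.

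Of the progesterone-responsive list 10 of 18 genes were higher in PRB with P4 and none lower (13 adjusted over the list alone; 9 without PRB P4 replicate 3), median 0.54 (camera, adjusted p = 1.97e-06; adjusted p = 0.110 with an estimated correlation). Steroid receptor targets held 6 higher of 15 (10 adjusted over the list alone), with Sgk1 at 1.36 and Zbtb16 at 1.35 (camera, adjusted p = 6.7e-06; adjusted p = 0.397 with an estimated correlation). Cell cycle genes held 10 lower of 19 and none higher (10 adjusted over the list alone; 9 without PRB P4 replicate 3), median -0.92, with Mcm5 at -1.47, Mcm6 at -1.28, Rrm2 at -1.24 and Mcm3 at -1.18 (camera, adjusted p = 5.07e-06; adjusted p = 0.842 with an estimated correlation). Endothelial markers held 4 higher of 10 (8 adjusted over the list alone), among them Tek at 0.59 and Pecam1 at 0.48 (camera, adjusted p = 0.000676; adjusted p = 0.757 with an estimated correlation). In the WNT and BMP list 2 were higher and 7 lower of 22, with Lgr5 at -1.02, Wnt7a at -0.997 and Wnt16 at -0.90. Esr1 (-0.45) and Nr3c1 (-0.33) were lower, among 1 higher and 4 lower of 15 receptors and coregulators (2 and 6 adjusted over the list alone). LIF signalling genes held 1 lower of 12, Jak1 at -0.15. Rrm2 lost the call under 4 of 17 alternatives, Jak1 under 2, Igj and Tek under 1, and Mir135a-2 under 6 of 16. The call count was 1548 without PRA P4 replicate 2, 1412 without PRA P4 replicate 4 and 1640 with the P4 libraries alone.

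**Figure D5:**
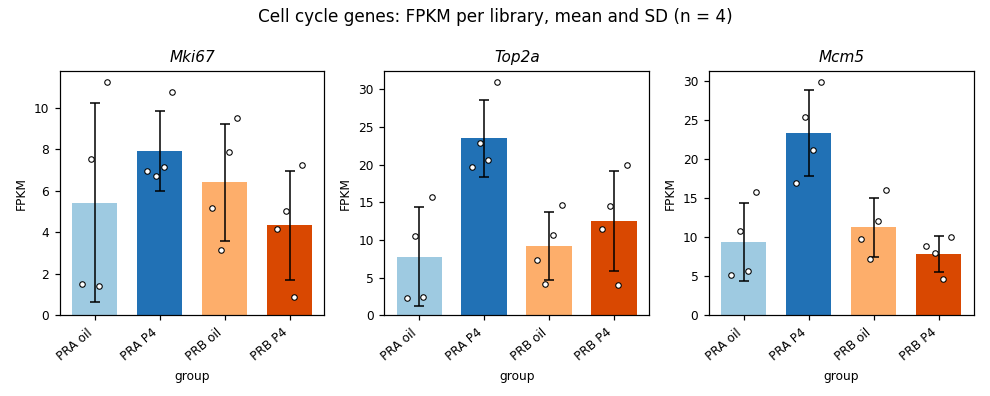
FPKM (y axis) of Mki67, Top2a and Mcm5 in each library (points) of the 4 groups (x axis), with bars for the mean and error bars for the SD, n = 4. Mki67 spread from 1.44 to 11.2 FPKM in PRA oil and was lowest in PRB P4 replicate 3, at 0.884 FPKM.

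The last comparison asked which genes responded to P4 differently in the 2 strains. Areg, which rose in both, rose more in PRB by 2.00 (SE 0.32, adjusted p = 0.00531), as did Fkbp5 by 1.27 (SE 0.21, adjusted p = 0.00771) and Il13ra2 by 1.20 (SE 0.25, adjusted p = 0.0254). With a pseudocount of 0.1 the value for Il13ra2 was 0.62 and was not called. Bmp4 stood at 27.6 and 14.0 FPKM with oil and P4 in PRA, and at 26.7 and 48.5 in PRB (difference of responses 1.76, SE 0.16, adjusted p = 0.000189). The genes Gins2 (-1.58), which acts at replication forks, Tcf19 (-1.55), Dscc1 (-1.5) and Gmnn (-1.46) had more negative responses in PRB. In all 352 features were called, 227 with a more positive and 125 with a more negative response in PRB. Of these, 153 changed in the same direction in both strains with the larger change in PRB, 36 with the larger change in PRA, 36 went in opposite directions, and 85 and 42 were called in PRB alone and in PRA alone.

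Large positive differences of responses were also those of Pate4 (3.03), Ms4a8a (2.77), Cyp2j11 (2.27), the secreted protein gene Scube2 (2.26), Cyp26a1 (2.13), Acsbg1 (2.11), Adh6a (2.11) and Slc5a5, the sodium iodide symporter gene (2.02). Other large negative ones included Tmem132c (-1.97), Sprr2e (-1.68), Igsf10 (-1.57), the natriuretic peptide gene Nppc (-1.53) and Cdkl1 (-1.51). The progesterone-responsive list held 4 called genes of 18, all more positive in PRB (8 adjusted over the list alone; 5 without PRB P4 replicate 3; camera, adjusted p = 0.00109; adjusted p = 0.224 with an estimated correlation), and steroid receptor targets 2 of 15, Fkbp5 and Pdk4 (also 2 adjusted over the list alone; 1 without PRB P4 replicate 3; camera, adjusted p = 0.00377; adjusted p = 0.769 with an estimated correlation). Mean Pdk4 was lower with P4 in both strains, from 7.49 to 2.57 FPKM in PRA and from 7.50 to 5.97 in PRB. Its positive difference thus marks a smaller decrease in PRB. The cell cycle list had a median of -1.03 (camera, adjusted p = 1.12e-08; adjusted p = 0.801 with an estimated correlation), with 1 called gene, Mcm3 (9 adjusted over the list alone), and none without PRB P4 replicate 3. Endothelial markers had no called gene (3 adjusted over the list alone; camera, adjusted p = 0.0219; adjusted p = 0.842 with an estimated correlation). Of the 18 camera calls over the 5 contrasts, 0 held with an estimated correlation. The count of 352 was 177, 229 and 163 without PRA oil replicates 1, 2 and 3, 183 and 155 without PRA P4 replicates 2 and 4, 201, 187 and 164 without PRB oil replicates 1, 3 and 4, and 190 without PRB P4 replicate 2. With 1 of the 16 libraries left out the 227 more positive responses numbered 120 to 330. The 125 more negative ones numbered 41, 69, 35 and 205 without PRA oil replicates 1 to 4, 40, 79 and 35 without PRA P4 replicates 2 to 4, 52, 51 and 36 without PRB oil replicates 1, 3 and 4, and 54 without PRB P4 replicate 2. Mcm3, Gmnn, Tcf19 and Pdk4 each lost the call under 15 of 24 alternatives, Gins2 under 7, Cyp26a1 under 6, Il13ra2 and Adh6a under 4, and, of 23 alternatives, Sprr2e under 8 and Nppc under 6.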

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

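The 3 tests of the cell cycle pattern were chosen after the result had been seen. Of 92 groups of 4 values examined, 6 held a library far from the other 3 by Dixon's criterion, and chance gives about 1 in 20 groups. Gbp2b was at 7.23 FPKM in PRA oil replicate 2 (others 8.30 to 8.37), Zfp868 at 37.2 in PRA oil replicate 1 (25.5 to 25.8), Mki67 at 10.8 in PRA P4 replicate 4 (6.72 to 7.14) and Rpl34 at 242.9 in PRB oil replicate 1 (228.1 to 229.5). In PRB P4 replicate 3, Pgr was at 78.5 (121 to 126) and Calca at 182 (18.2 to 36.6).

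The P4 responses of 352 features differed between the strains by the test of the difference itself, and the 39 given here are genes taken by the rule. Differences (PRB minus PRA, log2) were positive for Pate4 (3.03), Ms4a8a (2.77), Cyp2j11 (2.27), Scube2 (2.26), Cyp26a1 (2.13), Acsbg1 (2.11), Adh6a (2.11), Slc5a5 (2.02), Areg (2.00), Bmp4 (1.76), Slc6a14 (1.33), Fkbp5 (1.27), Car12 (1.27), Il13ra2 (1.20), Lcn2 (1.19), Greb1 (1.09), Npas2 (1.09), Gbp2b (1.03), Pdk4 (0.96), Rdh10 (0.86), Slc2a1 (0.75) and Ptgs1 (0.64). They were negative for Tpi1 (-0.26), Esr1 (-0.45), Cacna1c (-0.65), Mthfd1l (-0.99), Stc1 (-1.08), Wnt16 (-1.21), Lig1 (-1.31), Mcm3 (-1.42), Gmnn (-1.46), Dscc1 (-1.5), Cdkl1 (-1.51), Nppc (-1.53), Tcf19 (-1.55), Igsf10 (-1.57), Gins2 (-1.58), Sprr2e (-1.68) and Tmem132c (-1.97). Of 24 alternatives, the call was lost under 17 for Tpi1, 15 for Esr1, Car12, Pdk4, Mcm3, Gmnn and Tcf19, 14 for Cacna1c, 12 for Npas2, 11 for Greb1, 10 for Mthfd1l, 9 for Lcn2, 8 for Slc2a1, 7 for Gins2, 6 for Lig1 and Cyp26a1, and 4 for Adh6a and Il13ra2. Sprr2e lost it under 8 and Nppc under 6 of 23 alternatives. Gbp2b stood at only 0.221 FPKM with oil and 0.115 with P4 in PRB, where the pseudocount flattens a change. It was lower with P4 in both strains, and the size of its difference depends on the pseudocount. Mean Pdk4 was also lower with P4 in both strains, with the smaller decrease in PRB.

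Other splits of the same libraries were counted for each comparison. For the P4 response, 1 of 35 splits, the real one, called as many features in PRA (10760, highest other 1) and in PRB (10647, highest other 1). For PRB against PRA with P4 it was also 1 of 35 (2471, highest other 85). The real split is always counted, so 1 of 35 is the smallest share possible and cannot firmly exclude chance. Other splits for the P4 response mix oil and P4 libraries, which widens the spread within groups and leaves few calls. For the difference of responses 4 of 100 assignments called as many (352, highest other 613), 3 of them besides the real one. That share lies under 0.05 but rests on 100 draws, so chance was not firmly excluded for that count. With oil, 3 of 35 splits called at least the 18 features of the real one, and the highest other called 880, so chance cannot be excluded for that count. That split set PRA oil replicates 1 and 3 with PRB oil replicates 1 and 2 against the rest, and its size points to a structure among the oil libraries that does not follow the strains.

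Of 19 cell cycle genes 12 rose with P4 in PRA (camera, adjusted p = 0.0542; adjusted p = 0.938 with an estimated correlation) and 10 were lower in PRB than in PRA with P4 (adjusted p = 5.07e-06; adjusted p = 0.842 with an estimated correlation), with a median difference of responses of -1.03 (adjusted p = 1.12e-08; adjusted p = 0.801 with an estimated correlation). A single library as the whole source is argued against, since the median nearest to 0 with any 1 library left out was -0.74. For a lower share of a main tissue, the lowest median among the epithelial, stromal, smooth muscle and endothelial markers was -0.21. Each median less 1 SD over the list members lay above that of the cell cycle list. Many of these markers themselves changed with P4, so their medians need not follow the tissue share. A small population of dividing cells would also escape this test, so cell composition stays open. A shift of the strains or of the library rows (positions A for PRA and B for PRB) present without hormone would lower the list in PRB with oil, where its median was 0.20. The spread among oil libraries remains open for the rise in PRA, and a different action of the 2 receptor isoforms and the level of Pgr, which was higher in PRB with P4 by 0.57 (adjusted p = 0.00575), stay open as well, untested. With oil the mean of Pgr was also higher in PRB (83.5 against 64.9 FPKM), without a call.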

How the results depend on the processing

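The alternative without unmatched, microRNA and small nucleolar features, and the list counts without PRB P4 replicate 3, were chosen after the data had been seen. The counts of called features in the P4 responses and their overlap stayed within 1.5 times under every alternative but the minimum log2 change of 1, which gave 2190 in PRA and 2109 in PRB by its own construction, as well as 5 with oil, 204 with P4 and 90 for the difference of responses. With oil the count was 33 without a filter and 6 with the groups of the contrast only, and for PRB against PRA with P4 the latter gave 1640; the cause was not tested. Leaving out 1 library of the groups compared gave 8 to 19 features with oil, 1412 to 2612 with P4 and 155 to 494 for the difference of responses. All 16 libraries share 1 fit, and without PRB P4 replicate 3 the oil comparison gave 29 features, the 18 of the full fit among them. Of 18 list calls 0 were kept with an estimated correlation, and fry called 36. The replicate numbers did not pair the samples: 6 of 24 same-number pairs had correlated deviations over 0.1 (range -0.229 to 0.312) and 4 of 16 libraries correlated best with their own number. A replicate block gave 19 features with oil, 2569 with P4, 467 for the difference of responses (261 more positive and 206 more negative in PRB) and 19 list calls, adding the cell cycle list in PRA (adjusted p = 0.0123). Of 379 results for genes taken by the rule, 304 kept direction and call under all alternatives run, and 75 lost or gained the call under at least 1; in 6659 values, 446 lost the call, 362 of them on leaving out 1 library, 2 gained it and 1 reversed, Pgr in PRA at -0.0535 after quantile normalization (cause not tested). Depth limits weakly expressed features most, with about 109 fragments behind 1 FPKM of a 2 kb transcript.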

Other observations

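All tests in this part, the 6 gene lists included, were chosen after the result had been seen, except camera on the clock list, which was fixed beforehand. P4 raised genes of protein folding, ribosome production and sterol synthesis in both strains. In the unfolded protein response list 17 of 17 genes rose in PRA and 16 of 17 in PRB (17 adjusted over the list alone), with medians of 1.81 and 1.92, among them Sdf2l1 (4.02 and 3.72), Creld2 (3.03 and 2.91) and Hyou1 (2.78 and 2.91). All 20 ribosome biogenesis genes rose in both strains, with Ddx21 at 2.11 and 1.95. Cholesterol synthesis genes held 14 higher of 15 in each strain, with medians of 1.05 in PRA and 0.98 in PRB. Genes of amino acid and one-carbon synthesis held 9 higher and 1 lower of 10 in each strain, with Mthfd2 at 4.51 and 3.90 and Asns at 2.67 and 2.51. Glycolysis genes held 11 higher and 1 lower of 14 in PRA and 10 higher and 2 lower in PRB, with Hk2 at 2.27 and 2.40. Camera p-values adjusted over these 30 tests lay at 0.00711 or below for these lists in both responses, and at 0.233 or above with an estimated correlation. With P4, camera placed one-carbon (adjusted p = 0.00201), cholesterol (0.00291) and glycolysis genes (0.0152) lower in PRB than in PRA. It did not so place unfolded protein (0.353) or ribosome genes (0.0622). The difference of responses was more negative in PRB for one-carbon (median -0.46, camera, adjusted p = 0.000398) and ribosome genes (median -0.10, 0.0182). With an estimated correlation these strain values lay at 0.237 or above.

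Of 17 genes listed for DNA replication and its control 16 rose with P4 in PRA, with Uhrf1 at 2.09 and E2f1 at 1.77 (camera, adjusted p = 0.0063, and adjusted p = 0.603 with an estimated correlation). In PRB none rose and 3 fell, with Lig1 at -0.95. All 17 were lower in PRB than in PRA with P4 (16 without PRB P4 replicate 3), with a median of -1.42 (camera, adjusted p = 2.13e-12; adjusted p = 0.237 with an estimated correlation). For the difference of responses 5 were called (17 adjusted over the list alone; 4 without that library; camera, adjusted p = 9.35e-17; adjusted p = 0.237 with an estimated correlation). These genes were listed after the largest differences had been seen, so the counts are not independent evidence.

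Of the 18 features that differed between the strains with oil, 17 differed in the same direction between the P4 libraries, which come from other animals. There 13 were called, where 1.46 would be expected if the 2 contrasts were independent. Both contrasts use the same estimate of the spread for each feature, so they are not fully independent and 1.46 is likely too low. Of 14 called genes with a position, Tmem181 counted once, 5 had another within 5 Mb, such as Ints10, Zfp868 and Armc6 on chromosome 8, and random sets of genes had 1.06 on average (permutation test, one-sided, p = 0.013 from 10000 random sets). Chance placement is thus argued against. A candidate explanation for the 13 lasting differences is chromosome segments that the 2 strains inherited from different backgrounds, and an effect of the receptor isoforms without hormone stays open, untested. A difference between the library rows, which follow the strains with oil and with P4 alike, stays open too.

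All 4 clock genes that peak in the morning rose with P4 in both strains, with medians of 0.85 in PRA and 1.02 in PRB, and of 10 evening genes 6 fell in PRA and 7 in PRB and none rose, with medians of -0.80 and -0.998. The difference of the medians was 1.65 in PRA and 2.02 in PRB and was not tested against other genes. The clock list did not pass camera (adjusted p = 0.607 in PRA and 0.644 in PRB). Camera looks for a shift of a whole list in 1 direction, so it cannot decide whether 2 arms moved apart. Different collection times of oil and P4 animals may give this pattern, and so may an action of P4 on the clock; the 2 cannot be told apart, since the labels give no collection times.

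Gdpd3 took values of 24.1, 2.18, 2.44 and 21.3 FPKM in the 4 PRB P4 libraries. Ihh in the oil libraries ranged from 3.26 to 21.1 FPKM in PRA and from 7.10 to 30.6 in PRB.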
